A study of Mus musculus with 3 samples.

How the data were processed

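Bone marrow mononuclear cells came from 10 female mice aged 2 to 5 months in a model of immune-mediated bone marrow failure, 5 failure controls and 5 given granulocytic myeloid-derived suppressor cells (G-MDSCs). The labels describe the samples as mixed from the 10 animals, a table in the files lists 1 hashtag per animal, and libraries were made with a 10x Genomics V(D)J v1.1 kit. The RNA and surface antibody libraries were used. The receptor (V(D)J) library was not analysed here. Counts in the deposited files are whole-number UMI counts per gene and cell and antibody counts per protein and cell, made by the authors with Cell Ranger on the mm10 build, per the submitters' processing notes. Versions, the annotation and any filter on cells are not given in the sources used here. The deposited matrices held 29445 cells, 31053 genes named by symbol and 29 antibodies. The pooled matrix and the 10 per-animal matrices differed in 0 entries. No reference genome was used, so no coordinates are given.

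The arm of each animal rests on a match of numbers. The hashtag table lists animals 1 to 5 as controls and animals 6 to 10 as treated, and every barcode in a matrix ends in a number from 1 to 10. No barcode sequence occurred in more than 1 animal, where 514 would be expected had each animal been captured separately, which fits 1 shared capture split by animal. That the number is the animal's is an assumption. No text in the files states this tie outright, and the number is also that of the file. The plan fixed before the data were examined asked for text that ties a matrix to its arm and ruled out file numbers, so the match falls short of a strict reading of that plan. All comparisons between arms depend on it. Values per animal and the comparison of CD8 with CD4 T cells do not.

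Cells with at least 200 genes and under 10% mitochondrial UMIs were kept, and doublets called by Scrublet, as implemented in scanpy 1.11.5, were left out. Of all cells, 479 were doublet calls (1.63%) and 128 were at or over the mitochondrial limit, which left 28838. The 2000 most variable genes without receptor segments, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1.0 with seed 0 gave the clusters, with no batch integration. A cluster took the class with the highest share of its marker list detected in over 25% of its cells, with 3 or more markers, from 18 lists fixed before the data were examined. Cluster 12 had too few markers. Clusters 9 and 18 took the class of granulocyte-monocyte progenitors. Against cells of other classes, the 10 leading genes of cluster 9 held 4 markers of that class and 1 of neutrophils. Against all other cells, its leading genes mixed the progenitor markers Fcnb and Ms4a3 with the neutrophil markers Camp and Ngp. These clusters are therefore given by number, and their shares alone were compared after seeing the data. Cluster 19 first took the T cell class, with 5 markers, and was then left unnamed by a rule set after its genes were seen. Its 10 leading genes held 0 T cell markers and 1 marker of plasmacytoid dendritic cells. It is therefore not counted among the T-like cells. Its share was 0.262% ± 0.248 in controls and 0.725% ± 0.556 in treated animals (SD, n = 5 each). T-like cells were called CD8 or CD4 from antibody counts per 10000 of the cell's total, on a log2 scale with a pseudocount of 1, at the valley between the modes. Of 13625 T-like cells, 6272 were CD8, 6771 CD4, 412 carried both proteins and 170 neither.

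Raw counts were summed per animal and class where an animal had at least 20 cells, and tested with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. DESeq2 1.42.0 was an alternative. CD8 and CD4 T cells came from the same animals, so the animal was a block there. That block rests on the design: the deviations of an animal's CD8 and CD4 sums correlated between -0.0201 and 0.137, and 3 of 10 animals correlated best with their own partner. The 20 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Shares and protein levels were compared with two-sided exact permutation tests of 5 against 5 animals, whose smallest possible p is 0.00794. Clusters 9 and 18 and mast or basophil cells did not reach 20 cells in 3 animals of each arm and had no gene test.

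For each gene test the named genes were the 8 largest rises and 8 largest falls among called genes that moved the same way in at least 80% of animals and lay at or above the median expression, without receptor variable segments and unnamed gene models. The 3 members of each list with the smallest p were added. A test calling fewer than 16 genes names all, and one calling none names the 5 smallest p values. Within these, the list members printed for the arm comparisons were picked after their values were seen.

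On simulated counts with 200 changed genes, the test recovered 77.6% of 1.5-fold and 97.0% of 2-fold changes among 8473 genes for CD8 T cells, 68.7% and 97.0% among 7590 for CD4 T cells, 47.8% and 97.0% among 7705 for neutrophils, 29.9% and 73.1% among 5532 for monocytes, 22.4% and 74.6% among 5691 for erythroid cells, and 88.1% and 100% among 9480 for CD8 against CD4 T cells. Unchanged genes made up 7 of 190, 13 of 190, 21 of 182, 7 of 141, 7 of 132 and 13 of 205 calls, in that order. The changed genes left out the lowest expressed ones and genes were drawn independently, which favours recovery. Alternatives were another normalization, DESeq2, no filter on low counts, leaving out each animal, other cell filters and clustering resolutions, classes from UMIs, and a centred log ratio for antibodies. Correlations of protein with transcript are printed for 6 of 21 pairs in the results, and 1 further pair and 1 gene value are not reported here. Alternatives for the neutrophil, monocyte and erythroid classes other than the normalization were chosen after seeing the data. So was a minimum of 10 cells for the progenitor-rich erythroid cluster alone, which left out control replicate 5. A set of 12 comparisons of cell numbers, depth and cluster make-up was also unplanned. Intervals on shares are exact binomial at 95% and cover counting error only.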

Results

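The study asked how G-MDSCs, granulocytic cells that restrain immune responses, change immune-mediated bone marrow failure. Transcripts and 29 surface proteins were counted in the same marrow cells of 5 failure controls (replicates 1 to 5) and 5 G-MDSC-treated mice (replicates 6 to 10). The files held 1040 to 5322 cells per animal, with 3471712 to 21686654 UMIs, at least 1460 UMIs in each cell and medians of 2342 to 3557. Cells in the files numbered 1798 ± 972 in controls and 4091 ± 1136 in treated animals (SD, n = 5 each; exact permutation p = 0.0238, adjusted p = 0.19 over 12 unplanned tests). Each animal's arm was taken from the number that ends its barcodes, matched to the numbered animals of the hashtag table, and every comparison between arms rests on that match, which no text in the files states.

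The kept cells included T-like, neutrophil-like, monocyte, mast or basophil and erythroid cells in very different proportions from animal to animal. The lowest UMI count was 1460 to 1463 in every animal, so shares cover only cells at or above that level. T-like cells made up 14.9% of control replicate 1 (exact 95% interval 13.7 to 16.1) and 92.8% of control replicate 3 (91.2 to 94.2). Neutrophil-like cells ran the other way, at 60.5% in control replicate 1 and 1.095% in control replicate 3. Treated replicate 9 held 85.7% T-like and 1.20% neutrophil-like cells, while the other treated animals held 30.2 to 40.6% T-like cells. CD8 cells were between 35.2% and 65.1% of the CD8 and CD4 T cells.

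CD8 T cells averaged 34.8% ± 19.4 of cells in controls and 19.9% ± 9.24 in treated animals (SD, n = 5 each), and all 5 treated animals lay below the control median. Mast or basophil cells averaged 0.998% ± 0.703 and 3.797% ± 2.60, neutrophils 22.0% ± 25.4 and 35.9% ± 20.2, and all T-like cells 65.7% ± 32.9 and 45.8% ± 22.7. By exact permutation tests, no share passed after adjustment over 11 shares. The smallest p that 5 against 5 animals allow is 0.00794, at which a single share could not pass this adjustment. A difference in 1 class alone is therefore neither shown nor excluded. The adjusted p was 0.415 for CD8 T cells and for mast or basophil cells (unadjusted 0.0476 for the latter, higher in 4 of 5 treated animals than the control median), and 0.655 for T-like cells and for neutrophils. CD4 T cells averaged 27.6% and 24.1%, clusters 9 and 18 together 3.07% and 4.50% and monocytes 2.67% and 3.72% (adjusted p = 0.943 each, exact permutation). Alone, cluster 9 (1224 cells), led by Fcnb with the neutrophil granule genes Camp and Ngp, held 2.70% and 3.81% and cluster 18 (206 cells), led by the progenitor genes Elane, Prtn3 and Mpo, 0.373% and 0.692% (adjusted p = 0.683 each over these 2, exact permutation). Erythroid cells averaged 3.32% and 3.38% (adjusted p = 0.992) and CD8 cells among CD8 and CD4 T cells 54.1% and 46.2% (adjusted p = 0.415, exact permutation). The unnamed cluster led by MHC class II genes held 2.02% and 2.15% (adjusted p = 0.943) and the one led by Ccr9 and Il1rl1 0.262% and 0.725% (adjusted p = 0.415, exact permutation).

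**Figure D1:**
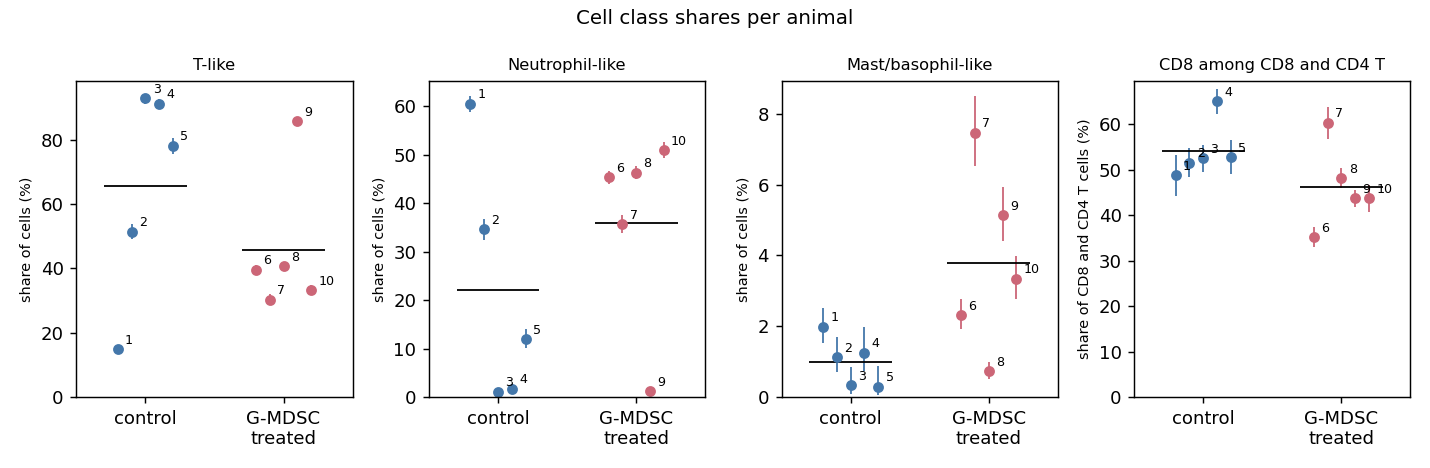
Share of each class per animal, in percent of cells (the last panel in percent of CD8 and CD4 T cells), by arm; points are animals with their numbers, bars exact 95% binomial intervals and black lines arm means. T-like cells lie between 14.9% and 92.8% in controls and between 30.2% and 85.7% in treated animals.

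CD8 T cells carried more killing machinery than CD4 T cells of the same animals. Gzma, a granzyme of cytotoxic granules, was higher by 3.07 ± 0.15 on the log2 scale (SE, n = 10 animals; 620 ± 209 against 72.6 ± 20.4 CPM, SD; edgeR adjusted p = 7.13e-14, higher in 10 of 10 animals). Prf1, which encodes perforin, was higher by 1.94 ± 0.07 and Gzmb by 1.86 ± 0.08. The glycolytic enzyme gene Eno3 rose by 3.14 ± 0.15, the lectin receptor gene Klre1 by 2.15 ± 0.12 and the receptor constant gene Tcrg-C2, a member of a family of similar segments whose counts are therefore uncertain, by 2.85 ± 0.18. Lat2, Wdr95, Sept4 and Ociad2 completed the 8 largest rises, at 2.49, 2.33, 2.24 and 2.10.

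The 8 largest falls were of genes higher in CD4 T cells. Cd40lg, the ligand that helps B cells and dendritic cells, differed by -4.89 ± 0.10 between CD8 and CD4 T cells, and Tnfrsf4, the receptor OX40, by -4.06 ± 0.07 (27.2 ± 4.82 against 468 ± 66.7 CPM). The chemokine gene Ccl1 differed by -5.54 ± 0.15, the proglucagon gene Gcg by -5.17 ± 0.22, Igfbp7 by -4.93 ± 0.10, Asb2 by -3.89, the cytokine subunit gene Ebi3 by -3.88 and Podnl1 by -3.44. Each of these 8 was lower in CD8 cells of 10 of 10 animals.

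Of the cytotoxic list, 10 of 14 measured genes rose and 3 fell. All 9 regulatory T cell genes fell, among them Il2ra (-3.73) and Tnfrsf18 (-1.90), and all 8 T helper genes tested fell, among them Icos (-2.14), with Cd4, which defines the class, left out of that list. Interferon gamma response genes fell in 16 of 17, with Iigp1 at -2.26 and Socs1 at -1.44, and MHC class II genes in 5 of 5, with Cd74 at -2.26. These lists held with an estimated correlation (adjusted p = 0.0274 for cytotoxic, 0.000199 for regulatory, 0.00104 for helper, 0.0274 for interferon gamma and 0.0261 for MHC class II). Cd74 is also among the genes of carry-over RNA, which fell in 11 of 12. H2-Eb1 (-0.90) and H2-Ab1 (-0.79) stood at only 10.5 and 10.4 CPM in CD8 T cells, and neither passed with classes from UMIs (-0.43 and -0.16). For all 20 lists the counts were the same when adjusted over the list alone.

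Proliferation and biosynthesis genes were higher in CD8 T cells: S phase in 39 of 42 (Mcm6 0.83, Mcm2 0.85), G2 and M phase in 45 of 52 (Cks1b 0.90, Hmgb2 0.51), ribosome biogenesis and Myc targets in 10 of 11 with 1 lower (Fbl 0.76, Ncl 0.53), and oxidative phosphorylation in 11 of 11 (Cycs 0.67, Ndufa4 0.63). The adjusted p of these lists with an estimated correlation was 0.106, 0.218, 0.103 and 0.0986. Inhibitory receptor genes rose in 8 of 10, Cd160 by 2.01, and Ctla4 fell by 1.55 on the log2 scale (list adjusted p = 0.175 with an estimated correlation). Mki67 was detected in 22.4% of CD8 and 17.5% of CD4 T cells (medians over animals, each cell thinned to 1460 UMIs), against 7.73% of neutrophil-like cells. Without thinning these were 39.6%, 26.5% and 15.6%, at median depths of 3255, 2176 and 3301 UMIs.

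Type I interferon genes fell in 11 of 15 and MHC class I genes in 8 of 10 with 1 higher, H2-K1 at -0.40 (adjusted p = 0.253 and 0.106 with an estimated correlation). The naive and memory list held 2 rises and 5 falls among 10 genes, with Il7r at -2.49 and Cd27 at 0.62 (adjusted p = 0.253 with an estimated correlation), and immediate early genes fell in 5 of 10, Junb at -1.20 (adjusted p = 0.0769 with an estimated correlation). Apoptosis genes split 6 and 6 of 15, p53 targets 2 and 3 of 8, chemokines and receptors 5 and 4 of 10 and glycolysis genes 6 and 1 of 11 into rises and falls, with no list call by camera. The test fry, which asks whether a list's genes move one way and compares them with no other genes, called 18 of the 20 lists, among them glycolysis (adjusted p = 0.00872) and p53 targets (adjusted p = 0.0320). MDSC-associated genes fell in 9 of 10 and genes of carry-over RNA in 11 of 12 (adjusted p = 0.0409 and 0.0112 with an estimated correlation). These include the neutrophil genes S100a8 and S100a9, both at -0.54. Neutrophil gene UMIs were 20.3 per CD8 and 21.1 per CD4 cell, while total UMIs were 3819 and 2631 (medians over animals).

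In all, 4601 of 9480 genes passed by edgeR, 2327 higher and 2274 lower in CD8 T cells. Cd4, Cd8a and Cd8b1 define the classes and are no findings.

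**Figure D2:**
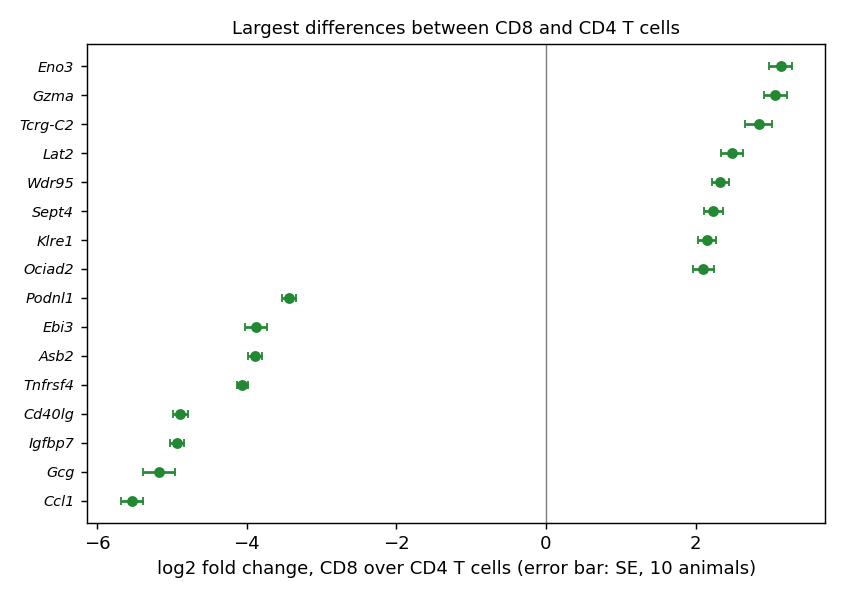
Log2 fold change of CD8 over CD4 T cells for the 8 largest rises and 8 largest falls; points are edgeR estimates over 10 animals and bars their SE. Values run from -5.54 for Ccl1 to 3.14 for Eno3.

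In CD8 T cells, no single gene was called between treated and control animals after the filter on low counts. By edgeR, 0 of 8473 genes passed, 315 had an unadjusted p under 0.05 where 424 would be expected by chance, and DESeq2 called 0, while 13 passed by edgeR with no filter on low counts. The smallest p values belonged to the cell cycle kinase gene Cdk6 (-0.41 ± 0.08 on the log2 scale, SE), Abhd8 (0.42 ± 0.09), the receptor segments Trbv17 (-3.31 ± 0.74) and Trbv13-2 (0.82 ± 0.20), whose similar sequences make their counts uncertain, and Arih1 (0.51 ± 0.12), with adjusted p of 0.764 for the first 3. Gzmb stood at -0.20 ± 0.10 and Xcl1 at 0.78 ± 0.32. Of the lists, G2 and M phase genes lay lower (12 of 52 above 0, Nusap1 at -0.24) and regulatory T cell genes higher (5 of 7 above 0, Ikzf2 at 0.35, Izumo1r at 0.28) with the preset correlation (adjusted p = 0.047 each), and not with an estimated correlation (adjusted p = 0.859 and 0.335). No member of any list passed when adjusted over the list alone. Without control replicate 2, 1 gene passed. Trbv17 stood at -1.85 without control replicate 3, which held 2018.7 CPM against 40.0 to 386 in the other controls, Ikzf2 at 0.21 without control replicate 3, Xcl1 at 0.47 without control replicate 4, and Nusap1 at -0.11 and -0.37 without control replicates 5 and 3.

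In CD4 T cells, Penk, which encodes the opioid peptide precursor proenkephalin, was lower in treated animals. It fell by 1.33 ± 0.20 on the log2 scale (SE; 119 ± 42.7 CPM in controls, 47.6 ± 13.7 in treated animals, SD, n = 5 each; edgeR adjusted p = 0.0248) and lay below the control median in 5 of 5 treated animals. Penk was detected in 2.56% of CD4, 0.768% of CD8 T cells and 0.826% of neutrophil-like cells thinned to the same depth (medians over animals; 4.18%, 1.63% and 1.65% unthinned). It was the single call among 7590 genes, with 408 at an unadjusted p under 0.05, and DESeq2 called 2, while 36 passed by edgeR with no filter on low counts. The call was lost on leaving out any of control replicates 1, 2, 4 and 5 or treated replicates 7, 8 and 9, where the smallest adjusted p of the test was 0.0542 to 0.134, while the log2 change of Penk stayed between -1.48 and -1.10 on leaving out any 1 animal. Without control replicate 3 or treated replicate 6, 4 genes passed, Penk among them.

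Other named genes in CD4 T cells did not pass. The interferon-induced genes Ifit1, Ifit3 and Mx1 stood at 0.56 ± 0.17, 0.86 ± 0.31 and 0.69 ± 0.25, the cytokine gene Il21 at -0.63 ± 0.16, the granule gene Nkg7 at -0.21 ± 0.05, Tox at -0.28 ± 0.10 and Lag3 at -0.29 ± 0.11. As lists with the preset correlation, type I interferon genes (adjusted p = 3.62e-06, 13 of 15 above 0) and naive and memory genes (0.0495, Tcf7 at 0.39) lay higher, and S phase genes (1.50e-05, 3 of 40 above 0) and inhibitory receptor genes (0.000518) lower. With an estimated correlation the adjusted p was 0.253, 0.408, 0.838 and 0.408 in that order, and no member of these 4 lists passed when adjusted over the list alone. Of the other lists, Nkg7 in the cytotoxic and Il21 in the helper list passed when adjusted over the list alone.

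Neutrophil-like cells (4 controls, without control replicate 3) and monocyte-like cells (3 controls, without control replicates 3 and 4) gave no passing gene by edgeR among 7705 and 5532, with 296 and 153 at an unadjusted p under 0.05 and 0 by DESeq2 in both. With no filter on low counts 16 passed in neutrophils and 38 in monocytes. Summed counts per animal were very uneven, from 93601 to 8751539 UMIs in neutrophils and from 250824 to 2052855 in monocytes. In neutrophils the smallest p values were those of the metal transporter gene Slc11a1 (0.63 ± 0.14), Tlr2 (0.90 ± 0.20), Cxcl2 (1.27 ± 0.30), Nlrp3 (1.68 ± 0.39) and Tmem189 (0.60 ± 0.14), though mean Cxcl2 was 23.8 CPM in controls and 21.5 in treated animals. In monocytes they were those of Mtmr14 (-1.40), Ccdc125 (1.27), Hspb11 (1.13), Arhgap4 (0.83) and Xdh (0.58). With the preset correlation, S phase and interferon gamma genes lay lower in neutrophils. In monocytes G2 and M phase genes lay higher (30 of 38 above 0), interferon gamma genes (3 of 16 above 0) and MHC class II genes (0 of 7 above 0) lower, and S phase genes were called higher with 18 of 36 above 0. None held with an estimated correlation (smallest adjusted p = 0.896 in neutrophils and 0.936 in monocytes). Adjusted over the list alone, the immediate early genes Dusp1 (0.77) and Fos (0.72) passed in neutrophils and no other list member in either class. Without control replicates 1 and 5 in turn, 3 and 1 neutrophil genes passed. Tlr2 stood at 0.51 in neutrophils and Ccdc125 at 1.99 in monocytes without control replicate 1.

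Erythroid-like cells were the class in which many genes differed between arms. In treated animals, genes of ribosome assembly rose, among others: Npm1 by 0.77 ± 0.10 on the log2 scale, Ncl by 0.58 ± 0.10, Fbl by 0.53 ± 0.11, Gpatch4 by 1.15 ± 0.20, Ppan by 1.05 ± 0.21 and the mitochondrial import gene Chchd4 by 1.07 ± 0.20. The metallothionein gene Mt2 rose by 1.38 ± 0.17 (144 ± 47.0 to 390 ± 44.2 CPM, SD, n = 5 each; edgeR adjusted p = 0.000988, higher in 5 of 5), the galectin gene Lgals9 by 1.34 ± 0.16, and the MHC class II genes H2-Ab1, H2-Eb1 and H2-Aa by 1.20, 1.04 and 0.85. Transcripts typical of T cells were lower, Gzma at -2.22 ± 0.38, Cd7 at -1.87 ± 0.36, Ccl5 at -1.78 ± 0.39, Gzmb at -1.74 ± 0.31, Ccl4 at -1.70 ± 0.35, Trbc2 at -1.68 ± 0.38 and Gimap7 at -1.67 ± 0.37, as was the myeloid gene Wfdc17 at -2.13 ± 0.51. Cells with 3 or more UMIs of T cell markers were 71.3 to 86.4% of erythroid-like cells in controls and 41.1 to 64.5% in treated animals, and 75.5% of the genes that fell, 4.07% of those that rose and 45.1% of those tested had higher CPM in T-like than in erythroid-like cells.

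By list, 7 of 10 ribosome biogenesis genes rose and 0 fell (9 of 10 adjusted over the list alone), 3 of 6 MHC class II genes rose, 7 of 9 cytotoxic and 7 of 8 inhibitory receptor genes fell (3, 9 and 8 adjusted over the list alone), and 4 of 46 G2 and M phase genes fell (3 adjusted over the list alone; Cenpf -0.65, Ube2c -0.48, Mki67 -0.40). MHC class I genes fell in 3 of 10, H2-D1 at -0.59, and glycolysis genes in 3 of 9, Pkm at -1.44 (4 falls and 1 rise each adjusted over the list alone). MDSC-associated genes fell in 5 of 9, immediate early genes in 4 of 5 and genes of carry-over RNA in 1 of 12 (8, 5 and 10 adjusted over the list alone). The carry-over list includes the haemoglobin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2, which in this class are the cells' own transcripts. With the preset correlation 12 of 19 lists passed and with an estimated correlation 0, where the smallest adjusted p was 0.151. By fry 13 passed here and 0 in each of the other 4 classes compared between arms. In all, 1015 of 5691 genes passed by edgeR (418 higher, 597 lower in treated animals) and 892 by DESeq2.

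Erythroid-like cells fell into clusters labelled haemoglobin-rich (501 cells, 74.3% of them with a UMI of Hbb-bs) and progenitor-rich (418 cells, led by Car1 and Car2). The second label is a name only. That cluster held all 11 erythroid markers, and haemoglobin genes were among its leading genes against other classes. Its median UMIs per cell were 3.951 times the animal's median, against 0.861 in the haemoglobin-rich cluster. The progenitor-rich cluster made up 29.6% ± 10.8 of erythroid-like cells in controls and 51.3% ± 14.5 in treated animals (SD, n = 5 each, exact permutation p = 0.0317, adjusted p = 0.19 over 12 unplanned tests). In erythroid-like cells the neutrophil gene S100a9 stood at 35236 ± 14339 CPM in controls and 16146 ± 9588 in treated animals (edgeR adjusted p = 0.0589, lower in 5 of 5 treated animals than the control median). The share of neutrophil-like cells went the other way, at 22.0% of cells in controls and 35.9% in treated animals. Prss34, a mast and basophil marker, rose by 1.41 ± 0.47 in erythroid-like cells, and mast or basophil cells were 0.998% and 3.797% of the arms. Neither share passed between arms. The count of passing genes was 149 in the progenitor-rich cluster alone, 0 in the haemoglobin-rich cluster alone, 92 without cells holding 3 or more UMIs of T cell markers and 38 with the share of the progenitor-rich cluster as a covariate. It was 661, 592, 636 and 612 without control replicates 1, 4 and 5 and treated replicate 8. In the haemoglobin-rich cluster alone, Cenpf, Ube2c, Mki67, Fbl and H2-D1 turned direction, to 0.15, 0.34, 0.10, -0.034 and 0.0040.

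**Figure D3:**
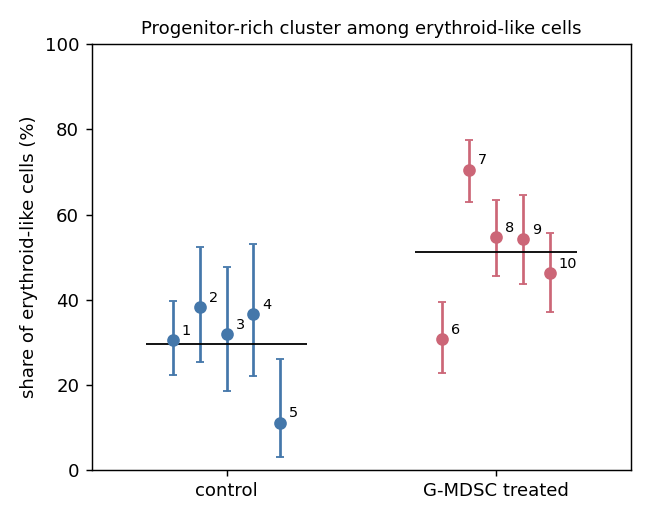
Share of erythroid-like cells in the cluster labelled progenitor-rich (led by Car1 and Car2) per animal, in percent, by arm. Points are animals with their numbers, bars exact 95% binomial intervals and black lines arm means. Controls lie between 11.1% and 38.2% and treated animals between 30.6% and 70.6%.

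Surface proteins were compared between arms in CD8 and CD4 T cells. In CD4 T cells the checkpoint receptor PDCD1 differed by -0.14 between treated and control animals (6.93 ± 0.05 against 7.08 ± 0.07, mean log2 of counts per 10000, SD, n = 5 each) and CD4 by -0.11, each lower in 5 of 5 treated animals (exact permutation p = 0.00794, adjusted p = 0.115). CD4 is also the protein that defined this class. The isotype controls IgG and IgG2b were 0.09 and 0.10 higher in CD4 T cells of treated animals (exact permutation p = 0.0317 and 0.0238, unadjusted). No protein passed in either class, and the smallest adjusted p in CD8 T cells was 0.46 (exact permutation), with 3 and 11 of 29 proteins under an unadjusted 0.05 in CD8 and CD4 T cells. The 11 include both isotype controls, and of the 11 only PDCD1 and CD4 were lower in treated animals. A shift in background signal was not tested. PDCD1 and CD4 lay at the smallest p that 5 against 5 animals allow, where so few proteins could not pass adjustment over 29. In CD4 T cells 12 proteins passed without treated replicate 6.

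Protein and transcript of the same gene were correlated across all kept cells, which are not independent replicates. Spearman's rho was 0.78 for ly6G, 0.62 for CD3 with Cd3e, 0.59 for CD8A, 0.48 for Ly6C with Ly6c2 and 0.46 for CD4. It was near 0 for IL4R (-0.01). Within T-like cells alone it was 0.07 for ly6G, -0.01 for CD3, 0.70 for CD8A, 0.47 for Ly6C and 0.51 for CD4, and the lowest values of a single animal were 0.11 for ly6G and 0.07 for CD3.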

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

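The tests of free RNA in T cells, of a mislabelled animal and of cell quality, and the rule on randomly removed cells, were chosen only after the results were seen. In 15 of 170 groups of animals 1 value stood far from the others, where chance gives about 8.5.

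Treated replicate 9 held 85.7% T-like and 35.9% CD8 T cells, far above the other treated animals (at most 40.6% and 18.996%). A mislabelled animal stays open: the lowest T-like share among controls, 14.89%, was not set apart from the other controls, which spread from 51.4% to 92.8%, which neither shows nor excludes a partner for an exchange, a single wrong label needs none, the share comparisons rest on these labels, and no measure independent of this outcome was at hand. Fewer or poorer cells may contribute and cannot be told apart from a true difference: of 3 measures, 1 lay beyond the other treated animals in the direction of poorer cells (median UMIs within CD8 T cells, 2670.5 against at least 2946.5). The number of cells lay inside their range, the mitochondrial share within CD8 T cells below it (1.549% against at least 1.580%), and within CD4 T cells neither UMIs nor mitochondrial share lay outside. A varied response to treatment was not tested.

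Many genes differed between arms in erythroid-like cells. Of 100 splits of the animals, 1, the real one with 1015 genes, gave as many. Of the other splits 5 called genes, and the highest gave 315, which argues against chance at no finer than 1 in 100. A different mix of the haemoglobin-rich and progenitor-rich clusters may account for part of the difference between arms. Sums rebuilt from 1 profile per cluster gave a median of 0.4487 of the observed log2 change, between the bounds set in advance. A change within the progenitor-rich cluster stays open, with a share of 0.1074 of the genes also past the threshold there, and so do T cells in doublets. Without cells carrying T cell marker UMIs a share of 0.0591 stayed past the threshold, which met the bound set for that cause, but 25 of 100 random removals of as many cells kept as few genes (60) or fewer (median 110, at most 504), so the loss of cells alone could give it, and treatment stays untested beside these.

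Neutrophil genes were lower in CD8 than in CD4 T cells. Neutrophils in doublets with CD4 T cells are argued against, because the median cell showed the difference too (log2 ratio of its neutrophil share -0.4992). Free RNA spread over larger CD8 totals is a candidate explanation, as neutrophil gene UMIs per cell were nearly equal (median log2 ratio -0.0923).

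The other values set apart were these. Control replicate 1 held 12.2% of cells in clusters 9 and 18, treated replicate 7 held 11.5% monocytes and 5.88% erythroid cells, CD8 cells were 65.1% of the CD8 and CD4 T cells of control replicate 4, and the progenitor-rich cluster was 11.1% of erythroid cells in control replicate 5. Trbv17 reached 2018.7 CPM in CD8 T cells of control replicate 3, Izumo1r 72.2 in treated replicate 6 and Ikzf2 103.9 in treated replicate 8. In erythroid cells, Fbl reached 495.16 CPM in treated replicate 7 and Ube2c 610.768 in treated replicate 9. In CD4 T cells, Penk stood at 71.0 CPM in treated replicate 10 and Ccl3 at 1118.6 in treated replicate 7. The log2 difference of Tcrg-C2 between CD8 and CD4 T cells was 5.02 in control replicate 2. The arm difference of Penk was itself different between CD8 and CD4 T cells, by 2.46 on the log2 scale (edgeR interaction, adjusted p = 0.0353, as for 2 of 9480 genes). Penk stood at 4.26 CPM in controls and 8.94 in treated animals in CD8 T cells.

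The single call in CD4 T cells was matched or exceeded by 23 of 100 splits, counting the real one, with 18 genes in the highest other, so chance cannot be excluded. A count of 0 is met by any split (100 of 100 in CD8 T cells and in neutrophils, 56 of 56 in monocytes), so the splits decide nothing there, and up to 39, 42 and 10 genes passed in another split. For CD8 against CD4 T cells, 1 of 100 draws, the real one, gave 4601 genes, which argues against chance at no finer than 1 in 100. Of the other draws 3 called genes, and the highest called 2992.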

How the results depend on the processing

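The alternatives for neutrophils, monocytes and erythroid cells other than the normalization were chosen after seeing the data. The count for CD8 against CD4 T cells stayed within 1.5 times under every alternative tried (4157 without the animal block, 3411 with classes from UMIs, 3515 by DESeq2, 4225 to 4535 on leaving out animals), and no call of a named gene was changed by the block. With no filter on low counts, 13 genes passed in CD8 T cells, 36 in CD4 T cells, 16 in neutrophils and 38 in monocytes, and DESeq2 called 2 in CD4 T cells; the cause was not tested. Leaving out 1 animal gave 0 to 1 genes in CD8 T cells, 0 to 4 in CD4 T cells, 0 to 3 in neutrophils and 592 to 1289 in erythroid cells. Erythroid genes numbered 149 in the progenitor-rich cluster alone, 0 in the haemoglobin-rich one, 92 without cells holding 3 or more T cell marker UMIs and 38 with the cluster share as covariate, all with fewer cells or 1 more term. In the haemoglobin-rich cluster alone these genes turned direction: Fbl (-0.034), H2-D1 (0.0040), Cycs (-0.0067), Cenpf (0.15), Ube2c (0.34), Mki67 (0.10) and Junb (0.11); the cause was not tested. With an estimated correlation, list calls went to 0 in each arm comparison and to 7 in CD8 against CD4 T cells. The median erythroid share, 3.18%, was 1.95% at resolution 2.0, 2.00% with doublets kept and 2.03% under 5% mitochondrial UMIs. Leaving out 1 animal, share differences (treated minus control, percentage points) lay between -32.5 and -13.0 for T-like cells, -21.8 and -9.30 for CD8 T cells, 8.67 and 23.5 for neutrophils, 0.705 and 3.71 for clusters 9 and 18, -11.4 and -5.15 for CD8 cells among CD8 and CD4 T cells, 0.292 and 0.609 for cluster 19, -0.567 and 0.301 for erythroid cells, -9.002 and 0.160 for CD4 T cells, -0.446 and 0.524 for cluster 12 and -0.901 and 1.65 for monocytes. The reversed values were -0.0387, -0.0205 and -0.567 (erythroid, without replicates 2, 4 and 7), 0.160 (CD4 T, without 3), -0.0970, -0.000265 and -0.446 (cluster 12, without 3, 5 and 7) and -0.901 (monocytes, without 7). In CD4 T cells 0 to 12 proteins passed. With a centred log ratio the correlation of protein with transcript reversed for CD28 (-0.15), IL4R (0.033), CTLA4 (-0.011), PTPRC (-0.023) and ADGRE1 (0.036); the cause was not tested.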

Other observations

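All comparisons here were chosen after seeing the data, and no explanation was tested. The receptor beta segments of CD8 T cells were unevenly used and differed between animals. Of 35 segments, Trbv17 took 59.4% of segment UMIs in control replicate 3 and Trbv29 took 42.6% in control replicate 2, and the effective number of segments ran from 2.73 to 11.5 over animals in CD8 and from 6.80 to 11.7 in CD4 T cells. The medians over animals were close, at 8.045 in CD8 and 8.213 in CD4 T cells. Trbv13-2 was the most used in CD4 T cells by median, at 19.004% of segment UMIs (10.8 to 31.7%).

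Smaller T-like clusters had their own leading genes: Foxp3 and Il2ra, genes of regulatory T cells, in a cluster of 446 cells, and Xcl1, Tcf7 and Slamf6 in a cluster of 392 cells. An unnamed cluster of 572 cells was led by the MHC class II genes H2-Eb1, H2-Aa and H2-Ab1 with Ighm, and an unnamed cluster of 167 cells by Ccr9, Il1rl1 and Gata3.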
